A study of Homo sapiens with 6 samples.

How the data were processed

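RNA of 3 irradiated and 3 control samples of HaCaT cells was extracted with Trizol as total RNA, and biotin-labelled cRNA was made by the manufacturer's standard Affymetrix method, per the labels' protocols. The deposited values are log2 expression values made by the authors with RMA, a method of background correction, quantile normalization and summary over the probes of a set, per the submitters' processing notes; its version is not given in the sources used here. The table holds 24733 probe sets for each of the 6 arrays. All columns share one distribution, with a largest gap of 0.00179 between column quantiles, so a shift of all transcripts in one direction would not show in these values. One column, the irradiated array of plate 1, holds 18030 distinct values and each other column 6978; the reason is not given in the sources used here. No 2 arrays held the same data: at most 121 probe sets had identical values on a pair of arrays. RMA values of dim probe sets are compressed toward the background, so fold differences of such genes are understated. For arrays, the number of arrays limits the precision.

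Probe sets correspond to 1 gene each and were named through the platform's dated annotation: 23934 had 1 gene symbol, 0 had several and 799 were left unnamed here. The unnamed sets stayed in the tests and were not reported by name. Classes of RNA were taken from a gene table of the human reference, matched by gene number. Genome positions are not given, because no build is named in the sources used here.

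Each plate held irradiated and control cells, per the labels and the design, so plate entered the fit as a block. As a check, deviations of same-plate arrays from their group means correlated across probe sets with r = 0.106, −0.0598 and 0.163 on plates 1, 2 and 3, against −0.166 to 0.0926 for arrays of different plates; the pairing rests on the design and not on this check. Replicates are plates of one experiment, and nothing says that they came from separate cultures grown apart. The p-values of single genes thus measure the spread between these plates, which may be technical in part.

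Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 prior variance for all probe sets, two-sided) on the log2 values as deposited, with plate and light as terms, no filter on dim probe sets and Benjamini-Hochberg adjustment over all 24733 probe sets at 0.05. Errors of log2 differences are standard errors from this fit, and 95% intervals use its moderated degrees of freedom. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists, and beside it with a correlation estimated from the data and with fry, which tests a list by itself. Lists, tests, groups and most alternatives were chosen before the data were examined. The lists cover light and stress responses, early genes, signalling, cell cycle, keratinocyte state, metabolism, clock, light receptors and markers of other cell types, and 472 of the 521 distinct genes written were measured.

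Genes were named by a rule with 3 parts. The first takes the 12 genes with the largest rise and the 12 with the largest fall past the adjusted threshold and of one sign on all plates, filled up where fewer pass with the smallest unadjusted p in that direction. The second takes the 2 members of each list with the smallest unadjusted p, and the third takes 23 genes fixed by name. As none passed, the first part gave 24 genes, those with the smallest unadjusted p among genes of one sign on all plates.

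The test was checked on simulated data, with variances drawn from the prior that limma fitted and 24733 probe sets with 3 plates. Over 5 runs it recovered 7.2% of planted changes of 0.5 log2 units, 81.6% of 1, 93.6% of 1.5 and 96.8% of 2, with 5 false calls in a run on average. Over these runs 250 changes of each size were planted. So many true changes relax the adjusted threshold, and a gene that changed alone would be found less often. The list test found a planted shift of 0.3 in a list of 20 genes in 20 of 20 runs and called 1 unchanged list over all runs of 30 such lists each. The simulated genes vary independently, which real genes do not, so the list check shows the best case.

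Alternatives were no plate block, plate as a random block, a trend or a robust prior variance, filters at the median and at the lower quartile of expression, renewed quantile normalization, centring on array medians, an adjusted p of 0.1, a least log2 change of 0.5, and each plate left out. Array weights, leaving out the irradiated array of plate 1 without a block, protein-coding genes alone, and an estimated correlation with arrays left out were added after seeing the data. A choice between probe sets of a gene was planned and could not be made, as each gene has 1.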

Results

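The experiment profiled HaCaT cells, a spontaneously immortalised human keratinocyte line that still stratifies and differentiates in culture. Cells received blue light with a peak wavelength of 453 nm for 7.5 min at 23 mW/cm² from a distance of 55 mm, a dose of 10.35 J/cm², and were harvested 1 h later. Control cells received no light. Each of 3 plates held both irradiated and control cells and gave 1 array of each kind, so there were 6 arrays in 2 groups of 3. Biotin-labelled cRNA from total RNA was hybridised to Affymetrix arrays with 24733 probe sets, 1 per gene. The median log2 signal of each array was 4.69 and the signals ran from 3.53 to 13.92. The study concerned the effect of blue light dose on keratinocyte proliferation, and the comparison asked which transcripts differed 1 h after this single dose.

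No transcript passed the test between irradiated and control cells. Of the fixed gene lists, 2 passed only camera with its preset correlation, and by small amounts: most genes of the G2 and M phases of the cell cycle lay higher (20 of 23, median log2 difference 0.060, a ratio of 1.04) and most targets of TGF-beta and BMP signalling lower (9 of 12, median −0.11, a ratio of 0.927). Neither passed with an estimated correlation (adjusted p = 0.816 for each with an estimated correlation) or by fry (adjusted p = 0.389 and 0.458 by fry), and neither passed without plate 3. Among single genes, the early growth response factor EGR1 had a log2 difference of 0.69 ± 0.140 and the neutrophil chemokine CXCL8 one of −0.58 ± 0.086 (irradiated minus control, ± SE of the limma fit, n = 3 plates, as for all gene values that follow), and neither passed after adjustment. The dioxin-responsive cytochrome CYP1A1, at −0.04 ± 0.082, lay close to 0.

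limma with plate as a block found 0 probe sets higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.957. At an unadjusted p under 0.05 there were 529 probe sets higher and 644 lower, in all 1173 where 1236.65 were expected by chance, and 10 had an unadjusted p under 0.001 where chance gives 24.733. Without the plate block the count past adjustment was also 0 and 1233 probe sets had an unadjusted p under 0.05. This closeness to chance depended on the arrays used. Without plate 1, more probe sets had an unadjusted p under 0.05 than chance gives, and without plate 2 or plate 3 fewer. The number was also above chance without a block and without the irradiated array of plate 1, a setting chosen after seeing the data. Whether these shifts follow light was not tested. The median absolute log2 difference was 0.055, and 24.9% of probe sets had the same sign on the 3 plates, where chance gives 25%. The log2 differences of plates 1 and 2 correlated across probe sets with r = −0.0019, those of plates 1 and 3 with r = −0.0191 and those of plates 2 and 3 with r = 0.0754; probe sets are not independent replicates. The median probe set had a 95% interval of ± 0.18 on the log2 scale, a ratio of 1.13. On simulated data with this spread and many changed probe sets, the test recovered 81.6% of changes of 1 log2 unit and 7.2% of changes of 0.5. Where few genes change the adjusted threshold is stricter, so these shares overstate the power for a few changed genes. MIR3137, at 1.02, had an adjusted p of 0.957 (limma). A change of 0.5 in a single gene would rarely be found with 3 plates, and one of 1 could be missed.

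The irradiated array of plate 1 stood apart from the other 5 arrays. Its correlations with them were 0.9915 to 0.9932, against 0.9971 to 0.9983 among the others, and 226 of its probe sets lay more than 1 log2 unit from the mean of the other 5, against 3 to 13 on each other array. Short structured RNAs made up most of the probe sets far above: of 194 more than 1 log2 unit above, 163 belonged to small nucleolar RNAs, which guide modification of ribosomal RNA, to small nuclear RNAs, to small Cajal body RNAs or to vault RNAs. The median deviation on that array was 0.81 for 313 small nucleolar RNAs (95% bootstrap interval 0.61 to 1.01), 1.45 for 18 small nuclear RNAs, 0.73 for 23 small Cajal body RNAs and 2.18 for 4 vault RNAs. The largest single values, chosen after they were seen, were those of the spliceosomal RNAs RNU5B-1 (4.40) and RNU12 (4.0) and of SNORA28 (3.70). Protein-coding transcripts had a median of −0.0083 and long noncoding RNAs one of 0.0052, but the array also spread more widely in general. The SD of the deviations of 17753 protein-coding probe sets was 0.212 on it and at most 0.139 on the others, and the SD of the irradiated minus control differences of all probe sets was 0.270 on plate 1, 0.175 on plate 2 and 0.157 on plate 3. On plates 2 and 3 the median irradiated minus control difference of the small nucleolar RNAs was −0.0044 and −0.00098, against 0.81 on plate 1. Every plate 1 value includes this array.

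**Figure D1:**
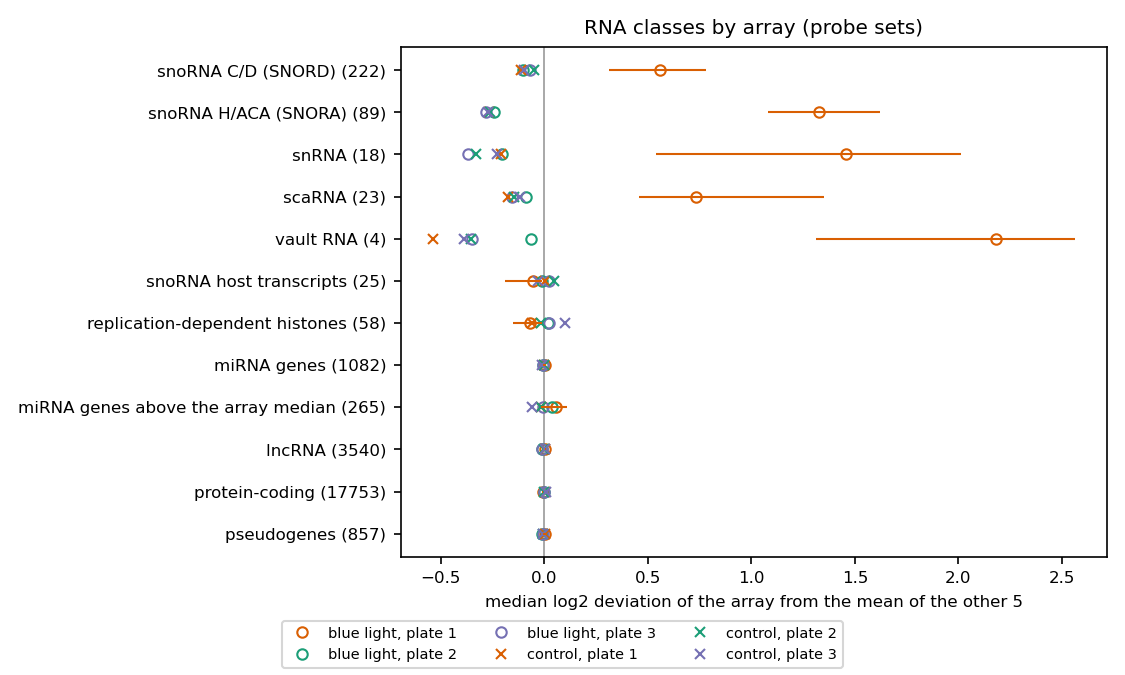
Median log2 deviation of each array from the mean of the other 5 arrays, on the horizontal axis, for 12 classes of RNA with their numbers of probe sets; circles are irradiated and crosses control arrays, colours are plates, and the line on the irradiated array of plate 1 is a 95% bootstrap interval of the median over probe sets. That array lies at 0.56 to 2.18 for the 5 short structured classes, while host transcripts, histones, long noncoding and protein-coding RNAs lie near 0 on every array.

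Since no gene passed, the 12 with the smallest unadjusted p in each direction are given as values that did not pass. The rule took only genes with the same sign on the 3 plates. The higher set included PLEKHM1 (0.73 ± 0.061), an adaptor for fusion of late endosomes and autophagosomes with lysosomes, and ATP6V1B1 (0.38 ± 0.056), a subunit of the proton pump that acidifies vesicles. It also held the brain-type creatine kinase CKB (0.48 ± 0.056), TEAD2 (0.47 ± 0.055), a transcription factor of the Hippo pathway, and EID3 (0.91 ± 0.121), PIGH (0.47 ± 0.066), a subunit of the enzyme that starts the synthesis of GPI anchors, and C8orf74 (0.81 ± 0.098). UGT1A5, a glucuronosyltransferase whose transcript shares exons with the other UGT1A genes, had 0.48 ± 0.069, so its signal cannot be assigned to that gene alone. The remaining 4 were MIR3137 (1.02 ± 0.072), the pseudogene NMRAL2P (0.92 ± 0.078), the T cell receptor constant segment TRBC2 (0.58 ± 0.054) and LOC642361 (0.46 ± 0.065).

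The lower set held the cytokine genes CXCL8 (−0.58 ± 0.086) and IL1B (−0.38 ± 0.058), which encodes interleukin-1 beta. NUAK2, a kinase related to AMPK, had −0.52 ± 0.057, and GPCPD1, which cleaves glycerophosphocholine, had −0.49 ± 0.053. ARRDC3, an arrestin-domain protein, had −0.64 ± 0.103, RASSF10 had −0.52 ± 0.081, GMCL1 −0.40 ± 0.064 and TMEM135 −0.32 ± 0.050. The noncoding members were MIR1204 (−0.65 ± 0.076), LOC100132077 (−0.43 ± 0.062), MIR3160-1 (−0.45 ± 0.069) and the pseudogene POLR2J4 (−0.41 ± 0.065).

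**Figure D2:**
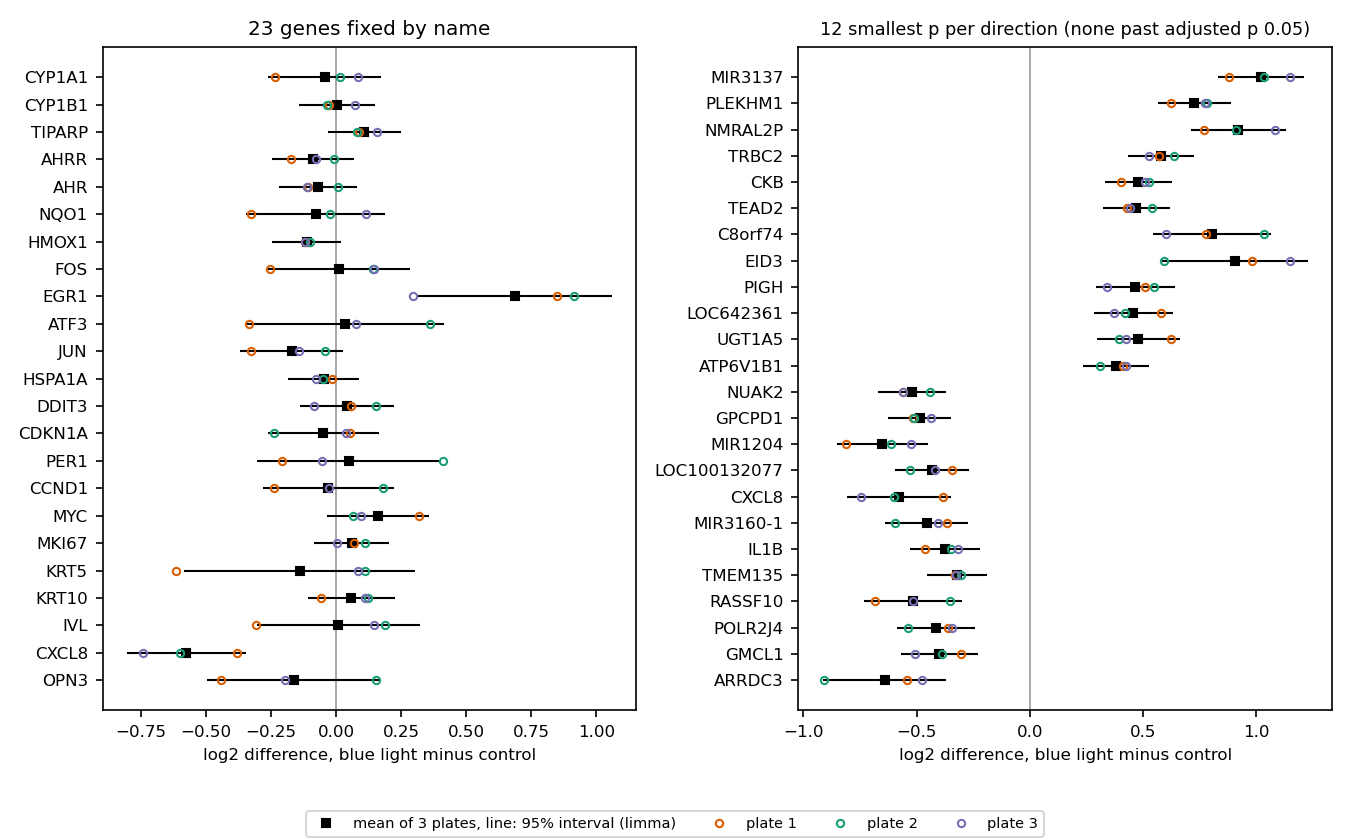
Log2 difference, irradiated minus control, on the horizontal axis for the 23 genes fixed by name and for the 12 genes with the smallest unadjusted p in each direction; open circles are the 3 plates, squares the mean of the plates and lines the 95% interval from limma. The intervals of EGR1 and CXCL8 leave out 0 in the fixed set, and none of the genes shown passed adjustment. The 12 and 12 were picked for their small p and one sign on all plates, so their intervals are shown for description.

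Of the 23 genes fixed by name, EGR1 and CXCL8 had an unadjusted p under 0.05. EGR1 was at 0.85, 0.91 and 0.30 on plates 1, 2 and 3, with a 95% interval of 0.31 to 1.06. The intervals of the other 21 genes included 0, with the highest upper bound, that of ATF3, at a ratio of 1.33. Genes read out for the aryl hydrocarbon receptor lay close to 0: CYP1A1 at −0.04 (95% interval −0.26 to 0.17, a ratio of 0.834 to 1.13), CYP1B1 at 0.0022 ± 0.055, TIPARP at 0.11 ± 0.053, the receptor's repressor AHRR at −0.09 ± 0.059 and the receptor AHR at −0.07 ± 0.056. The oxidative stress genes NQO1 and HMOX1, quinone reductase and haem oxygenase, had −0.08 ± 0.101 and −0.11 ± 0.050. The AP-1 genes FOS and JUN had 0.011 ± 0.102 and −0.17 ± 0.075, and ATF3 had 0.034 ± 0.144. The heat shock gene HSPA1A had −0.05 ± 0.051, the stress factor DDIT3 0.04 ± 0.068, the cell cycle inhibitor CDKN1A −0.05 ± 0.081 and the clock gene PER1 0.05 ± 0.133. The proliferation genes CCND1, MYC and MKI67 had −0.03 ± 0.095, 0.16 ± 0.073 and 0.06 ± 0.054. The keratins KRT5 of basal cells and KRT10 of differentiating cells had −0.14 ± 0.167 and 0.06 ± 0.063, and involucrin (IVL), a protein of the cornified envelope, 0.0084 ± 0.117. The opsin OPN3 had −0.16 ± 0.126. For KRT5 and IVL the value of plate 1, −0.62 and −0.31, lay apart from those of plates 2 and 3, and without plate 1 the genes were at 0.10 and 0.17, against −0.27 and −0.08 without plate 2 and −0.25 and −0.06 without plate 3. The sign of several of these small values depended on the plates used. With each of plates 1, 2 and 3 left out in turn, CYP1A1 was at 0.05, −0.07 and −0.11, NQO1 at 0.04, −0.11 and −0.18, FOS at 0.14, −0.06 and −0.06, and ATF3 at 0.22, −0.13 and 0.013. In the same order PER1 was at 0.18, −0.13 and 0.10, CDKN1A at −0.10, 0.05 and −0.09, CCND1 at 0.08, −0.14 and −0.03, and OPN3 at −0.021, −0.32 and −0.14. MYC was at 0.08, 0.21 and 0.19, MKI67 at 0.06, 0.04 and 0.09, DDIT3 at 0.03, −0.013 and 0.10, and KRT10 at 0.12, 0.026 and 0.03. JUN was at −0.09, −0.24 and −0.19, AHRR at −0.04, −0.13 and −0.09, and AHR at −0.05, −0.11 and −0.05. Without a block and without the irradiated array of plate 1, CYP1A1 was at 0.17 and CYP1B1 at 0.16. Of the 104 genes named by the rule, 28 moved by over 1.5 times or changed sign without plate 1, 25 without plate 2, 18 without plate 3 and 33 without a block and without the irradiated array of plate 1. None of the 24 with the smallest p did. They were picked for small p and one sign on all plates, which favours this, so it is no sign of stability.

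In the 31 gene lists, 472 distinct genes were measured. None of them passed over all genes; adjusted over the list alone, 3 passed: CXCL8 and IL1B in the NF-kB list (adjusted p = 0.0212, limma) and MT1E in the metallothionein list (adjusted p = 0.0260, limma). That adjustment leaves the looks at 31 lists uncorrected, so a few such members can arise by chance. Camera called 2 lists with its preset correlation of 0.01 and 0 with an estimated correlation, where the smallest adjusted p was 0.816. Fry called 0 lists, with a smallest adjusted p of 0.367 for shifts one way and 0.149 for change in either direction. Fry and camera with an estimated correlation had few residual degrees of freedom, so these counts of 0 decide little. Adjusted camera p values of the other 29 lists ran from 0.171 to 0.971. The sign of the list median changed in at least 1 setting for 20 of the 31 lists, and for 15 when a plate was left out. The median moved by over 1.5 times or changed sign for 22, 17 and 20 lists without plates 1, 2 and 3 and for 21 without a block and without the irradiated array of plate 1. Only 5 lists kept their median within that range in all of these: G2 and M phase, TGF-beta and BMP, YAP, hypoxia and glycolysis, and keratinocyte activation. Values for members of the lists are given as above, and none of these members passed over all genes.

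The G2 and M phase list held 20 higher and 3 lower genes with medians of 0.056, 0.027 and 0.049 on plates 1, 2 and 3. BUB1, a kinase of the spindle checkpoint, had 0.16 ± 0.058 and the mitotic kinase PLK1 0.17 ± 0.067, or 0.10 without plate 2. The camera test gave an adjusted p of 0.0186 with the preset correlation, adjusted p = 0.816 with an estimated correlation and 0.389 by fry. With the preset correlation it gave 0.111 without plate 2 and 0.268 without plate 3, and 0.0918 when probe sets below the median expression were left out. The list passed there at 0.0232 without plate 1 and 0.00917 without a block. In settings added after seeing the data it gave 0.00920 with array weights and 0.0181 on protein-coding genes. Without a block and without the irradiated array of plate 1 it gave 0.00272. The estimated correlation of this list was −0.036, so correlation between its genes does not account for the larger p with it. Camera with an estimated correlation uses only the few residual degrees of freedom of the fit, which enlarges p. The G1 and S phase list had 6 of 20 genes higher, 14 lower and a median of −0.05, and it did not pass. Its median was 0.011 without plate 1. In it the S phase cyclin CCNE2 had −0.36 ± 0.060 and the replication licensing factor CDT1 0.26 ± 0.076. Of 7 replication-dependent histones 3 were higher and 4 lower, with a median of −0.013 and H2BC21 at −0.16 ± 0.063. H2BC12 had −0.16 ± 0.090, or −0.05 without plate 1, −0.24 without plate 2 and −0.018 without a block and without the irradiated array of plate 1.

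Targets of TGF-beta and BMP signalling were 3 higher and 9 lower, with medians of −0.19, −0.09 and −0.125 on plates 1, 2 and 3. The inhibitory SMAD7 had −0.43 ± 0.085 and ID3, an inhibitor of basic helix-loop-helix factors, −0.28 ± 0.070. The camera test gave an adjusted p of 0.0314 with the preset correlation, adjusted p = 0.816 with an estimated correlation and 0.458 by fry. With the preset correlation it gave 0.118 without plate 1 and 0.182 without plate 3, 0.0665 with array weights, 0.0803 without a block and without the irradiated array of plate 1, and 0.0918 without the dimmer probe sets. The list passed there at 0.0190 without plate 2, 0.0432 without a block and 0.0357 on protein-coding genes.

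The lists for light, oxidative and proteotoxic stress did not pass. Aryl hydrocarbon receptor targets were 5 higher and 11 lower with a median of −0.07, and plate 1 had a median of −0.24 where plates 2 and 3 had −0.00098 and 0.08; ALDH3A1, an aldehyde dehydrogenase, had −0.12 ± 0.083, or −0.026 without plate 1. Without plate 1 the median of this list was 0.028. NRF2 antioxidant genes were 14 higher and 9 lower with a median of 0.032: thioredoxin reductase TXNRD1 had 0.39 ± 0.073 and sulfiredoxin SRXN1 0.22 ± 0.067. Without plate 1 this list passed camera with the preset correlation at an adjusted p of 0.0232, with a median of 0.045, and there it had adjusted p = 0.874 with an estimated correlation. Without plates 2 and 3 its medians were 0.0125 and 0.0075 and it did not pass (adjusted p = 0.335 and 0.709, preset correlation). Heat shock genes were 12 higher and 5 lower (median 0.034), with the cochaperone FKBP4 at 0.14 ± 0.053 and HSPA4L at −0.26 ± 0.067. The unfolded protein and integrated stress list was 12 higher and 9 lower (median 0.021, or −0.0144 and −0.0334 without plates 2 and 3). Within it CHAC1, which degrades glutathione, had 0.49 ± 0.106 (0.83 without a block and without the irradiated array of plate 1) and DDIT4, an inhibitor of mTORC1, −0.60 ± 0.157, or −0.38 without plate 1. In the p53 and DNA damage list 7 genes were higher and 14 lower (median −0.04, or −0.0049 without plate 1 and −0.0982 without plate 2), with GADD45A at 0.33 ± 0.074 and SESN1 at −0.21 ± 0.058. Metallothioneins and zinc genes were 4 higher and 5 lower. Their median was −0.09, but 0.00016, 0.0078 and −0.09 on plates 1, 2 and 3, −0.0107 without plate 1 and 0.0052 without a block and without the irradiated array of plate 1. MT1E had −0.40 ± 0.068 and MT1F 0.26 ± 0.101 (0.15 without plate 1), and these near-identical genes can share signal.

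Signalling and immune lists did not pass either. Immediate early genes were 17 higher and 15 lower with a median of 0.0059, and after EGR1 the smallest p was that of KLF6, at 0.28 ± 0.064. NF-kB and cytokine genes were 11 higher and 11 lower; their median was 0.011 while their mean was −0.05 and the camera direction down. Interferon-stimulated genes were 9 higher and 10 lower (median −0.0069), with IRF7 at 0.19 ± 0.060 and ISG15 at 0.19 ± 0.060. EGF receptor ligands and feedback genes were 4 higher and 9 lower (median −0.05), with the ligands EPGN and HBEGF at −0.27 ± 0.062 and −0.27 ± 0.067. YAP targets were 10 higher and 4 lower (median 0.05), with the matricellular CCN1 at 0.29 ± 0.072 and ARHGEF17 at 0.29 ± 0.107, or 0.16 for ARHGEF17 without plate 2. Glucocorticoid targets were 3 higher and 7 lower (median −0.011), with ERRFI1 at 0.27 ± 0.088 and CEBPD at −0.26 ± 0.114, or −0.42 without plate 1 and −0.17 without plate 3 for CEBPD. Without a block and without the irradiated array of plate 1, EPGN was at −0.16 and HBEGF at −0.12.

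Keratinocyte lists did not pass on the 3 plates. Differentiation genes were 14 higher and 11 lower with a median of 0.0015, and OVOL1, a transcription factor of epidermal differentiation, had 0.26 ± 0.055 and CALML5 0.15 ± 0.051. Only 11 of the 25 members of this list lay above the array median in signal, and CALML5 had a mean control signal of 4.06. Without plate 1 this list passed at an adjusted p of 0.0232 with the preset correlation and a median of 0.06, and there it had adjusted p = 0.874 with an estimated correlation. Its median was −0.0267 without plate 2 and 0.026 without plate 3, where it did not pass (adjusted p = 0.927 and 0.308, preset correlation). Basal markers were 5 higher and 5 lower, with a median of 0.0069, a mean of −0.0037 and the camera direction up. The integrin ITGA6 had −0.14 ± 0.067 (−0.08 without plate 1) and the keratin KRT15 0.16 ± 0.087 (0.08 without plate 2, 0.26 without plate 3). Genes of keratinocyte activation were 3 higher and 6 lower (median −0.04), with LCN2 at −0.32 ± 0.079 and SERPINB4 at −0.42 ± 0.210. SERPINB4 was at −1.02 on plate 1 and at −0.23 and −0.013 on plates 2 and 3. Without a block and without the irradiated array of plate 1, LCN2 was at −0.11 and OVOL1 at 0.39.

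Metabolic and light-sensing lists did not pass. Steroid hormone metabolism was 15 higher and 9 lower (median 0.035, or −0.0038 without plate 3), with HSD11B2, which inactivates cortisol, at 0.32 ± 0.072 and HSD17B1 at 0.14 ± 0.054. Of the 24 steroid genes measured, 9 lay above the array median in signal. Cholesterol synthesis was 4 higher and 12 lower (median −0.07, or −0.0359 without plate 1), with SC5D at −0.30 ± 0.096 (−0.17 without plate 1) and STARD4 at −0.17 ± 0.060. Hypoxia and glycolysis was 4 higher and 13 lower (median −0.08), with VEGFA at −0.21 ± 0.053 and ANKRD37 at −0.16 ± 0.061. Subunits of respiratory complex IV and cytochrome c were 4 higher and 6 lower. Their median was −0.09, or −0.0435 without plate 1 and −0.0125 without a block and without the irradiated array of plate 1, with COX6C at −0.17 ± 0.065 and COX7C at −0.21 ± 0.095, or −0.11 and −0.10 without plate 2. Haem synthesis was 5 higher and 4 lower, with a median of 0.016 (0.11 without plate 1, −0.0208 without plate 2 and −0.0422 without plate 3), a mean of −0.00055 and the camera direction up; UROS had −0.11 ± 0.051 and UROD −0.36 ± 0.180, or −0.10 without plate 1. Clock genes were 11 higher and 7 lower with a median of 0.005, a mean of −0.014 and the camera direction down; BHLHE40 had −0.26 ± 0.078 and NPAS2 −0.20 ± 0.064. Opsins and light-gated channels were 5 higher and 6 lower (median −0.0014). OPN4 had 0.10 ± 0.064 (0.05 without plate 2, 0.15 without plate 3) and OPN5 −0.10 ± 0.067 (−0.17 without plate 2, −0.06 without plate 3). Their mean control signals of 4.64 and 4.51 lie near the array median. Cytosolic ribosomal proteins were 8 higher and 11 lower (median −0.028), with RPL7 at −0.16 ± 0.073 (−0.09 without plate 3) and RPL35 at −0.11 ± 0.054. RPL7 had a mean control signal of 4.20, below the array median. Without a block and without the irradiated array of plate 1, HSD17B1 was at 0.06 and STARD4 at −0.10.

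Markers of cell types that a keratinocyte line should lack did not pass. Most were dim: 3 of 10 fibroblast, 2 of 9 melanocyte, 2 of 10 leukocyte and 2 of 10 endothelial markers lay above the array median in signal. Fibroblast markers were 3 higher and 7 lower (median −0.04, or −0.087 without plate 1 and −0.0046 without plate 2), with COL1A1 at −0.08 ± 0.056 and COL1A2 at −0.08 ± 0.064, or −0.13 and −0.028 for COL1A2 without plates 1 and 2. Melanocyte markers were 5 higher and 4 lower (median 0.015), with MITF at −0.21 ± 0.082 (−0.11 without plate 1) and SOX10 at 0.20 ± 0.132 (0.028 without plate 2 and 0.34 without plate 3). Leukocyte markers were 5 higher and 5 lower, with a median of 1.4e-05, a mean of −0.033 and the camera direction down; CD68 had −0.23 ± 0.093 and LYZ −0.07 ± 0.055, or −0.11 and −0.04 without plate 1. Endothelial markers were 3 higher and 7 lower (median −0.04, or −0.0115 without plate 1 and −0.0662 without plate 2), with TEK at −0.12 ± 0.063 (−0.08 without plate 3) and KDR at −0.06 ± 0.057 (−0.11 without plate 2).

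**Figure D3:**
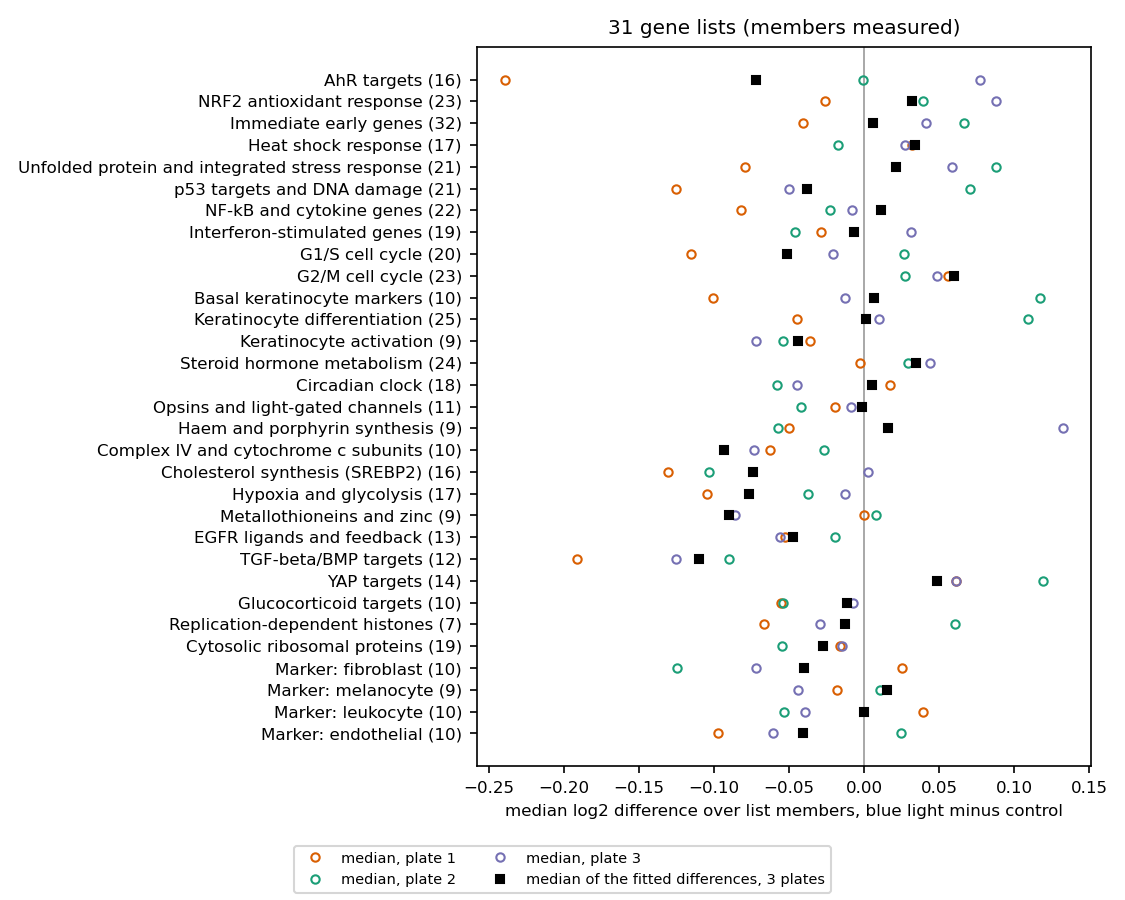
Median log2 difference, irradiated minus control, over the measured members of each of 31 gene lists, on the horizontal axis; open circles are the 3 plates, squares the median of the fitted differences, and the number of members measured follows each name. The 3 plates lie on one side of 0 for 11 lists, among them the G2 and M phase list and TGF-beta and BMP targets. These 2 passed camera with the preset correlation only (adjusted p = 0.816 for each with an estimated correlation). Plate 1 lies at −0.24 for aryl hydrocarbon receptor targets.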

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

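Array weights, the fit without a block and without the irradiated array of plate 1, the fit on protein-coding genes, and an estimated correlation with arrays left out were chosen after seeing the data. In all 17 settings run for counts, 0 probe sets were higher and 0 lower after blue light; the smallest adjusted p ranged from 0.168 (no block and no irradiated array of plate 1) to 0.995 (without plate 2). Of the alternatives, renewed quantile normalization and median centring moved no value of the genes named by the rule by more than 0.00053 and so say nothing about stability. A choice between probe sets of a gene was not run because each gene has 1. Of the 104 genes named by the rule, 92 kept their sign in every setting. Sign changes came in 11 when a plate was left out, in 5 without a block and without the irradiated array of plate 1, and in 1 with array weights. None of the 104 passed in any setting. The 24 genes with the smallest p kept their sign, which their choice by one sign on all plates fixed for plates left out. Of the list medians, 20 of 31 changed sign in some setting: 5, 8 and 6 of them without plates 1, 2 and 3, 8 without a block and without the irradiated array of plate 1, and 5 without dimmer probe sets.

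The number of gene lists passing, 2 with the plate block, was also 2 with no replicate block and 2 on protein-coding genes, so the pairing changed no call. It was 0 among probe sets at or above the median expression, 0 with an estimated correlation, 0 by fry and 1 with array weights, where the G2 and M phase list passed. Leaving out a plate gave 0 to 3 lists: 3 without plate 1, 1 without plate 2 and 0 without plate 3. Without a block and without the irradiated array of plate 1 there were 3 with the preset correlation: NRF2 genes (adjusted p = 0.00272, limma's camera), the G2 and M phase list (0.00272) and keratinocyte differentiation (0.0161). With an estimated correlation the number was 0 there (adjusted p = 0.534, 0.534 and 0.677 for those lists) and 0 without each plate, where 2 plates leave little to estimate it from. The settings with fewer plates test with fewer arrays; the cause of the other moves was not tested. Median signal over the arrays was 4.68 against a floor of 3.58, so for many dim transcripts a change would be compressed.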

Other observations

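The tests of blue light and of recovery or labelling for short RNAs were chosen only after the result was seen. On the irradiated array of plate 1, 32 probe sets lay more than 1 log2 unit below the mean of the other 5 arrays, 24 of them protein-coding. The lowest, chosen after their values were seen, were the ribosomal protein gene RPS26 (−1.75), the zinc finger gene ZNF487 (−1.45) and TXNIP, an inhibitor of thioredoxin (−1.32). Other genes in that set included SNRPE, a core protein of spliceosomal particles (−1.10), and CERS3, a ceramide synthase of the epidermal barrier (−1.09). In irradiated minus control difference, a measure unlike these deviations, TXNIP was at −0.17 and −0.19 on plates 2 and 3. MicroRNA genes above the array median had a median deviation of 0.058 on that array, far below the other short classes. For 58 replication-dependent histone probe sets, a larger set than the 7 measured genes of the gene list, it was −0.07.

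The high short structured RNAs of that array were weighed against 3 explanations. Blue light as their cause is argued against by plates 2 and 3, where the larger of the median irradiated minus control differences of the small nucleolar RNAs was −0.001, against 0.81 on plate 1. For transcription of host genes, only 25 noncoding host transcripts, the SNHG genes and GAS5, were examined. Their median deviation on that array was −0.0563 (95% bootstrap interval −0.192 to −0.011), so these transcripts did not rise with the small nucleolar RNAs. Other host genes were not examined, so this explanation is argued against only for that set. Recovery or labelling of short RNAs in that one preparation may account for the pattern and stays open: 45 small nuclear, Cajal body and vault RNAs had a median of 1.0334 (0.621 to 1.42), but they are part of the pattern and so cannot test it. Its column also holds 18030 distinct values where each other column holds 6978, so another way of summarising that array before deposit stays open too and was not tested. The low protein-coding genes were not tested for a cause.

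More genes of the fixed lists than other genes had an unadjusted p under 0.05: 46 of 472, or 9.75%, against 4.62% of other named genes, 21 of them higher and 25 lower. The count of 46 had been seen when its tests were written, and the results of those tests had not. Expression level alone is argued against, as 10000 draws of genes matched on mean expression gave a median of 25, a central 95% range of 17 to 35 and at most 44, a share of 1e-04 that is the smallest such draws can give; the draws treat genes as independent, and list genes are not. Among the 4 splits of the arrays that part each plate pair, only 1, the real one, gave as many as 46, and the highest other gave 33; 4 splits are too few for a share under 0.05. Without the block, the highest other split gave 70 list genes and 2824 probe sets in all, against 45 and 1233 for the real split. With the block, swapping the labels on plates 2 and 3 gave 1455 probe sets at an unadjusted p under 0.05, against 1173. A grouping that does not follow light can thus give as many list genes. The split with 70 also called more probe sets in all, so its count does not show as large an excess over other genes. The share of other genes was not computed for these splits. A response to light may account for part of the excess, and a difference between cultures that list genes follow more than other genes may too. These counts cannot tell them apart.

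For the count of probe sets past adjustment, all 4 of the splits that part the plate pairs gave as many as the real one, 0, and the highest other gave 0; without the block all 10 splits into 3 and 3 gave 0, and the highest other was 0. With a real count of 0 every split gives as many, so these counts say nothing about chance, and both sets of splits are too few for a share under 0.05. At an unadjusted p under 0.05 the split of both plate 1 arrays and the control of plate 2 against the rest gave 2824 probe sets and 70 list genes, against 1233 and 45 for the real split without a block. That split was picked as the highest of the others after their values were seen, and whether it reflects a structure of the samples was not tested.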
